A study of Mus musculus with 6 samples.

How the data were processed

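Expression was measured in mouse embryonic stem (ES) cells on Illumina bead arrays, in which each probe is carried by many beads and read as 1 brightness. Per the labels' protocols, the cells grew on mitomycin C-inactivated embryonic fibroblasts (feeder cells) with 15% serum and the cytokine LIF. They were electroporated with a shRNA vector and selected with puromycin from 24 h after transfection for 48 h. The labels put 3 samples in a control group and 3 in a group that received a shRNA against Ep400 (shEp400). Nothing in the labels says that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

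The deposited values of the main table are signal intensities on a linear scale for 45281 probes, one array per sample, each with a detection p-value per the file headers. Intensities were not scaled between arrays, and no background had been subtracted, as their range showed (lowest signal 77.6). GenomeStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The authors' processed values, a deposited matrix of linear intensities, ranked the probes of each array exactly as that array's own signals did (rank correlation 1) and had a median of 114 on every array, which is the pattern of quantile normalization. Its scale was therefore linear and its columns uncentred. It served as an alternative only.

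The deposited platform annotation gave 1 gene symbol to 34885 probes, several to 18 and none to 10378. Symbols were compared with a RefSeq table (assembly GRCm38.p6) through Entrez IDs, which matched 34807 probes and changed 0 symbols. The array's own genome build is not given in the sources used here, so no coordinates are reported. Probes with several symbols were left out.

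Log2 values were computed from the signal intensities with neqc in limma 3.58.1 (R 4.3.3), which estimates the background from the detection p-values, adds an offset of 16 and normalizes by quantiles. Probes with a detection p under 0.01 on at least 3 arrays were kept, and each gene was represented by its probe with the highest mean over the 6 arrays. This left 9736 genes from 14238 named probes. Of the 3280 genes with more than 1 such probe, 21 had probes called in opposite directions. Groups were compared with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment at 0.05, without covariates. Log2 changes are shEp400 minus control and are given with their standard errors (SE). The fit had 4 residual degrees of freedom, and the number of arrays limits its precision. Where a probe was above background on no array of a group, only a bound is given. The bound is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes.

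Gene lists were tested with camera in limma at a preset correlation of 0.01, over 26 lists with at least 5 measured members, and again with a correlation estimated per list and with fry. The lists covered the Tip60-p400 complex, other chromatin remodellers, general and naive pluripotency, formative and primed pluripotency, mesoderm and definitive endoderm, extraembryonic endoderm, neuroectoderm, trophectoderm, Polycomb-type developmental regulators, germline genes, 2-cell-stage-like genes, feeder fibroblast markers, p53 targets, DNA replication, mitosis, MYC targets, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, interferon response, Wnt targets, heat shock, immediate early genes, and autophagy and lysosome. The lists, the test and all but 3 of the other settings tried were fixed before the data were examined.

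The genes named were fixed by rule. They are Ep400, the 12 largest rises and the 12 largest falls among called genes with separate groups and a proper symbol, up to 2 rises and 2 falls per list, called members of the Tip60-p400 list, and Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Cdkn1a, Myc, Kat5 and Trrap. Where another gene is named, the text says so.

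The steps were tested on simulated signals for 3 against 3 arrays, with 2 noise models. With each probe's own moderated SD, on 11070 genes, 87.2% of genes changed 3-fold were recovered, 53.2% of those changed 2-fold and 4.08% of those changed 1.5-fold. With one SD for all probes, on 11118 genes, the shares were 93.6%, 57.4% and 8.16%. In the simulation with each probe's own SD, 2 of the 72 calls fell on unchanged genes. Each simulation tested 98 genes changed 1.5-fold, 47 changed 2-fold and 47 changed 3-fold, while 4251 genes were called in the data. With so few changed genes the adjustment is stricter, so these shares do not give the recovery in this comparison. Normalization with a large share of genes changed was not tested. In the simulation with each probe's own SD camera called a planted list and 0 of 25 random lists. Its noise was independent between genes and its random lists held only unchanged genes. It therefore does not test camera on lists whose genes are correlated.

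Alternatives covered the background correction, the normalization, the filter on dim probes, the rule for several probes, the variance model, array weights, the deposited matrix, and leaving out each array in turn. After the data had been seen, 3 more were added: centring on the probes detected on every array, the feeder markers' mean as a covariate, and the Tip60-p400 list without Ep400.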

Results

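The data were 6 expression arrays of mouse ES cells, 3 from cells that had received a control vector and 3 from cells that had received a shRNA against Ep400. Ep400 is the ATPase of the Tip60-p400 complex, which remodels chromatin and carries the acetyltransferase Kat5. The series concerns the function of chromatin remodellers in ES cells, and the comparison asks which transcripts differ when Ep400 is knocked down. Detected probes numbered 16096, 15441 and 15962 on the control arrays and 16439, 16152 and 17337 on the shEp400 arrays. The upper quartile of the signal lay between 141 and 195. All arrays lay on one slide, with the groups in separate neighbouring positions, so position and group cannot be told apart. The shEp400 arrays 1, 2 and 3 lay at positions C, B and A. A trend over these 3 arrays therefore cannot be told apart from slide position.

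Ep400 itself fell, from a normalized log2 signal of 9.62 ± 0.083 (SD, n = 3) in control to 9.04 ± 0.142 (SD, n = 3) in shEp400 cells (log2 change -0.58, SE 0.16, limma adjusted p = 0.0159). Its 3 shEp400 values all lay below the 3 control values. The value rests on 1 of its 3 probes, since the remaining probes were above background on 0 of 6 arrays. The call was lost with cyclic loess normalization (log2 change -0.42, adjusted p = 0.0631) and without control replicate 1 (-0.53, adjusted p = 0.0616). The median log2 change was -0.06 over all tested genes, -0.56 for general and naive pluripotency genes and -0.64 for the Tip60-p400 list without Ep400. These arrays alone thus do not tell a loss of the target from a wider fall.

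The knockdown arrays differed from control in a large share of the transcriptome. Of 9736 genes, 4251 changed (43.7%), 2005 of them higher and 2246 lower. Changes of at least 1.5-fold were called for 3671 genes. Rises were larger than falls: 222 genes rose at least 4-fold, and 24 fell as much. The groups' values were separate for 55.5% of tested genes, where chance gives 10%. With cyclic loess 2436 genes were higher and 1667 lower, so that 59.4% of called genes were higher, against 47.2% with quantile normalization. With 75th percentile scaling 1771 were higher and 2755 lower (39.1% higher), and with centring on the probes detected on every array, chosen after seeing the data, 42.3% were higher. The count changed at least 1.5-fold was 2016 without background correction and 2156 from the deposited matrix.

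Ankrd1, a nuclear protein of stretched muscle, rose 12.1-fold (log2 change 3.60, SE 0.23, limma adjusted p = 3.19e-05). Inhba, a subunit of activin, rose 9.15-fold, and the smooth muscle actin Actg2, detected on 1 of 3 control arrays, rose 7.94-fold. Gadd45g, a stress-induced gene, rose 8.11-fold and the chemokine Ccl5 rose 7.87-fold. Phf11a, whose probe was detected on 2 of 3 control arrays, rose 9.28-fold. Tdpoz8, detected on 1 of 3 control arrays, rose 10.7-fold and Pramel17 rose 7.91-fold. Both belong to families of similar copies, so their probes may read more than one copy. Serpinb2, a protease inhibitor, was detected on 0 control arrays and was at least 5.75-fold higher (limma adjusted p = 0.000168) with the background correction used. Its log2 change was 1.79 with normexp without negative controls and 1.28 without background correction, so this limit depends on the correction. Without background correction 35 of the named genes moved by over 1.5 times, and with the deposited matrix 31 did. Among the 35 were Ankrd1 (log2 change 2.60, from 3.60), Phf11a (1.84, from 3.21), Actg2 (1.45, from 2.99), Tdpoz8 (1.60, from 3.42) and Pramel17 (1.75, from 2.98). Genes named further below were among them too, such as Tdpoz4 (2.14, from 3.24), Hoxa5 (1.22, from 2.36), Sox2 (-1.01, from -1.60) and Gnl3 (-1.24, from -1.87). Ccl5 had a log2 change of 3.60 without shEp400 replicate 1.

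The steepest falls included Gtsf1l, which fell 6.96-fold (log2 change -2.80, SE 0.22, limma adjusted p = 3.5e-05). Gdf3, a TGF-beta family factor of pluripotent cells, fell 5.35-fold. Actn3, an actinin, fell 5.31-fold, the glutamate transporter Slc1a3 fell 5.14-fold, and Rragb, a GTPase of amino acid sensing, fell 4.79-fold. Qprt, an enzyme of NAD synthesis, also fell 4.79-fold, and the growth factor Fgf17 fell 4.61-fold. Cdca7 fell 4.71-fold, Nfkbid 4.53-fold, Gli2 4.45-fold and Pnma2 4.30-fold. Etv2, detected on 2 of 3 shEp400 arrays, fell 4.53-fold. Without background correction the falls of Actn3, Slc1a3, Rragb, Qprt, Fgf17, Nfkbid, Pnma2 and Etv2 were smaller by over 1.5 times, with log2 changes between -1.38 and -0.94.

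**Figure D1:**
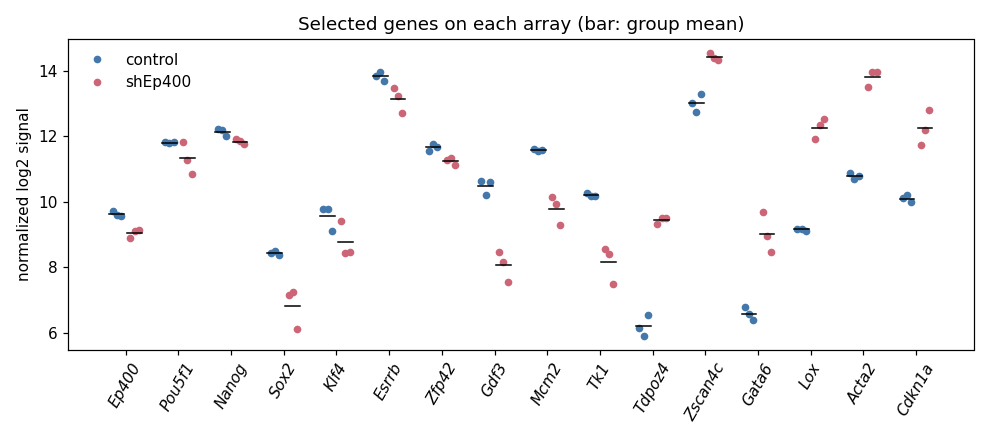
Normalized log2 signal (vertical axis) of 16 genes on each of the 6 arrays, with control in blue and shEp400 in red and the bar at each group's mean. Ep400 was lower by 0.58 on the log2 scale, while Lox and Acta2 were higher by 3.11 and 3.04.

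Markers of the feeder fibroblasts rose. Of 34 measured, 29 rose and 0 fell over all genes; adjusted over the list alone, 31 rose and 1 fell. Lox, which cross-links collagen, rose 8.63-fold (log2 change 3.11, SE 0.19) and the smooth muscle actin Acta2 rose 8.21-fold. The list's median log2 difference from control was 1.84, 2.23 and 2.43 on shEp400 arrays 1, 2 and 3. The list was higher by camera (adjusted p = 1.15e-16), and adjusted p = 0.246 with an estimated correlation. The Polycomb-type developmental regulators rose as well: 15 of 17 measured, from a list of 35, rose and 0 fell, also when adjusted over the list alone. A member undetected in control is tested only if all 3 shEp400 arrays detect it, so members that stayed silent are not counted. The list's medians were 0.94, 1.35 and 1.75 on shEp400 arrays 1, 2 and 3. Igf2, a growth factor, rose 5.39-fold and Hoxa5 rose 5.12-fold (camera adjusted p = 2.01e-07, and adjusted p = 0.246 with an estimated correlation).

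Genes of the 2-cell-stage-like state rose. Of 16 measured, from a list of 29, 14 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell. Here too members that stayed silent are not counted. Tdpoz4 rose 9.44-fold and Tcstv1 rose 7.02-fold, while the translation factor Eif1a fell 1.59-fold (camera adjusted p = 9.99e-10, and adjusted p = 0.246 with an estimated correlation). Zscan4c, the marker gene of this state and named after its values were seen, rose 2.63-fold. The list's medians on shEp400 arrays 1, 2 and 3 were 2.21, 2.11 and 2.09, beside feeder marker medians of 1.84, 2.23 and 2.43.

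DNA replication and G1/S genes fell: 33 of 41 fell and 1 rose, and adjusted over the list alone 35 fell and 1 rose. Tk1, thymidine kinase, fell 4.17-fold and Mcm2, part of the replicative helicase, fell 3.45-fold, while Ccnd1, cyclin D1, rose 2.63-fold (camera adjusted p = 9.17e-11, and adjusted p = 0.246 with an estimated correlation). Mitosis genes fell in 22 of 30 cases and 0 rose, and adjusted over the list alone 24 fell. The mitotic kinase Plk1 fell 3.14-fold and the spindle protein Nusap1 fell 3.08-fold (camera adjusted p = 1.47e-07, and adjusted p = 0.279 with an estimated correlation). The replication list's medians were -0.89, -0.99 and -1.43 on shEp400 arrays 1, 2 and 3, where feeder marker medians were 1.84, 2.23 and 2.43, and those of the mitosis list were -0.64, -0.92 and -1.31. Genes of ribosome biogenesis and other MYC targets fell in 27 of 37 cases and 0 rose; adjusted over the list alone, 28 fell. The nucleolar gene Gnl3 fell 3.65-fold and Ppat, of purine synthesis, fell 2.68-fold (camera adjusted p = 2.01e-07, and adjusted p = 0.246 with an estimated correlation). Myc itself, detected on 2 of 3 control arrays, did not pass the test (log2 change 0.43, SE 0.26, adjusted p = 0.206).

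Among general and naive pluripotency genes 17 of 36 fell, 3 rose and 16 did not pass; adjusted over the list alone, 18 fell and 3 rose. Tcl1 fell 3.96-fold and Sox2 3.03-fold, while Dppa3 rose 1.86-fold and Fbxo15 1.67-fold (camera adjusted p = 0.000341, and adjusted p = 0.412 with an estimated correlation). Klf4 fell 1.73-fold (adjusted p = 0.0482) and Esrrb 1.61-fold (adjusted p = 0.0246), and both calls were lost with cyclic loess and without control replicate 1 or 2 or shEp400 replicate 2 or 3. Pou5f1 had a log2 change of -0.49 (SE 0.23, adjusted p = 0.112), Nanog of -0.30 (SE 0.16, adjusted p = 0.147) and Zfp42 of -0.42 (SE 0.16, adjusted p = 0.054), and they passed in 4, 5 and 9 of the other settings fixed in advance. The call of Dppa3 was lost without control replicate 1 and that of Fbxo15 without control replicate 2 and with 75th percentile scaling. The list's medians on shEp400 arrays 1, 2 and 3 were -0.29, -0.55 and -0.94, where feeder marker medians were 1.84, 2.23 and 2.43. Formative and primed pluripotency genes were not called as a list (camera adjusted p = 0.389): 5 of 14 fell and 1 rose, also adjusted over the list alone. Otx2 fell 2.52-fold, Lefty1, whose call was lost without shEp400 replicate 3, fell 2.38-fold and Dusp6 rose 1.91-fold.

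**Figure D2:**
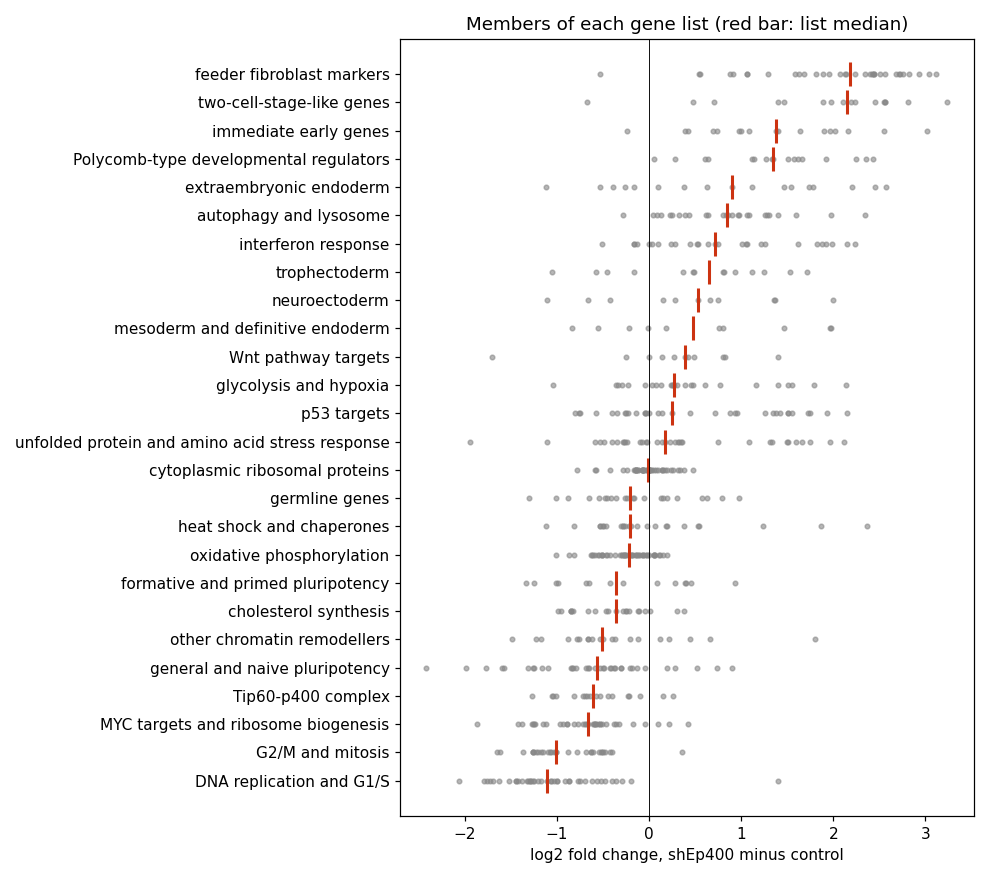
Log2 fold change (horizontal axis, shEp400 minus control) of each measured member of the 26 gene lists, 1 point per gene, with a red bar at the list's median. Feeder fibroblast markers lie highest with a median of 2.18, and DNA replication and G1/S genes lie lowest with -1.11.

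The Tip60-p400 list fell: 11 of 18 genes, the targeted Ep400 among them, fell and 0 rose, and adjusted over the list alone 12 fell (camera adjusted p = 0.00158, and adjusted p = 0.246 with an estimated correlation). Besides subunits of the complex, the list holds the histone variant genes H2az1 and H2az2, which are among those that fell. Without Ep400, in a test added after the data had been seen, 10 of 17 fell and 0 rose, and adjusted over the list alone 11 fell (camera adjusted p = 0.00235, and adjusted p = 0.246 with an estimated correlation). Meaf6 fell 2.42-fold, Mbtd1 2.08-fold, Ing3 2.06-fold, the helicase Ruvbl2 2.01-fold and Actl6a 1.76-fold. The list's medians on shEp400 arrays 1, 2 and 3 were -0.45, -0.54 and -0.61, where feeder marker medians were 1.84, 2.23 and 2.43. The histone variant genes H2az1 and H2az2 fell 1.62-fold and 1.56-fold, Kat5 1.44-fold and Yeats4 1.36-fold. Trrap fell 1.60-fold and was detected on 2 of 3 control and 1 of 3 shEp400 arrays. The calls of Kat5, Yeats4 and Trrap were each lost in at least 3 of the 6 fits that left out 1 array. Of the other chromatin remodellers 10 of 20 fell and 1 rose, and adjusted over the list alone 12 fell and 3 rose. Smarca1 fell 2.82-fold and Chd1l 2.34-fold, while Smarca2 rose 3.49-fold (camera adjusted p = 0.0285, and adjusted p = 0.246 with an estimated correlation). The medians of this list were -0.44, -0.52 and -0.58 on the same arrays. That list call was lost with 75th percentile scaling (adjusted p = 0.0528) and among probes detected on all 6 arrays (adjusted p = 0.0683). Without background correction the log2 changes were -0.52 for Meaf6 (from -1.28), -0.79 for Smarca1 (from -1.49) and -0.44 for Chd1l (from -1.23).

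Of the differentiation lists, those of extraembryonic endoderm and trophectoderm rose. Their measured members were 17 of 30 and 14 of 23, and members that stayed silent are not counted. Of 17 extraembryonic endoderm genes 9 rose and 1 fell, and adjusted over the list alone 10 rose and 2 fell. Gata6, a master regulator of that lineage, rose 5.46-fold, the basement membrane collagen Col4a2 rose 5.93-fold and Rhox5 fell 2.17-fold (camera adjusted p = 0.00196, and adjusted p = 0.246 with an estimated correlation). The 7 members not called included Hnf4a, Amn and Lama1 (log2 changes -0.39, -0.54 and -0.16), named after their values were seen. The list's medians were 0.77, 0.97 and 0.98 on shEp400 arrays 1, 2 and 3, where feeder marker medians were 1.84, 2.23 and 2.43. Entry into this lineage was not told apart from a larger share of feeder-cell RNA. Of 14 trophectoderm genes 9 rose and 2 fell, and adjusted over the list alone 9 rose and 3 fell. Krt8, a keratin, rose 2.89-fold, Id2, whose probe was above background on 0 control arrays, was at least 2.77-fold higher with the background correction used (log2 change 0.63 without it), Tfap2c fell 2.08-fold and Bmp4 1.37-fold (camera adjusted p = 0.0497, and adjusted p = 0.248 with an estimated correlation). That list call ended in 11 of the other settings, and the call of Bmp4 in 5 of the 6 fits that left out 1 array. Lists of mesoderm and definitive endoderm and of neuroectoderm did not pass (camera adjusted p = 0.0857 for each). In the first, 4 of 10 genes rose and 1 fell, also adjusted over the list alone, with Snai1 up 3.94-fold, Meis2 up 3.90-fold and Wnt3a, detected on 2 of 3 shEp400 arrays, down 1.79-fold, a call lost in 3 of the 6 fits that left out 1 array. In the neuroectoderm list 4 of 11 rose and 2 fell, and adjusted over the list alone 5 rose and 2 fell. Nes rose 3.98-fold, Sox11 rose 2.57-fold, Mapt fell 2.16-fold and Stmn2 1.59-fold, a call lost without control replicate 3 or shEp400 replicate 2. Germline genes did not pass (camera adjusted p = 0.455), with 3 of 22 higher and 4 lower, also adjusted over the list alone. Taf7l rose 1.97-fold and Brdt, whose probe was detected on 1 of 3 control arrays, 1.74-fold, a call lost without background correction, while Rec8 fell 2.47-fold and Tex11 2.02-fold. Wnt targets did not pass (camera adjusted p = 0.175), with 3 of 11 higher and 1 lower, also adjusted over the list alone. Apcdd1 rose 1.78-fold, a call lost without control replicate 1 or 3 or shEp400 replicate 2, and Notum, an inhibitor of Wnt, fell 3.27-fold.

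**Figure D3:**
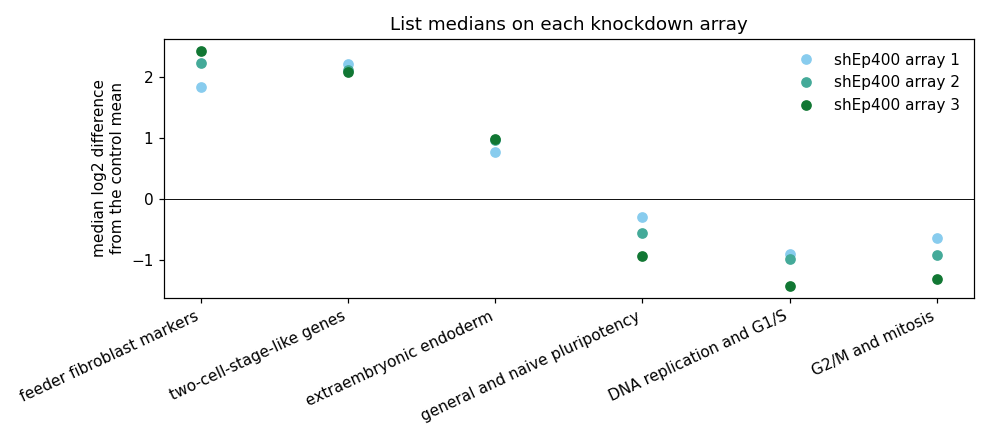
Median log2 difference from the control mean (vertical axis) of 6 gene lists on each shEp400 array, 1 point per array. The feeder fibroblast markers lie at 1.84, 2.23 and 2.43 on arrays 1, 2 and 3 and the 2-cell-stage-like genes at 2.21, 2.11 and 2.09.

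Of the 6 stress and signalling lists, 4 rose and 2 did not pass. Of 17 immediate early genes 14 rose and 0 fell, also adjusted over the list alone, Gadd45g most and Jun, an AP-1 subunit, 5.87-fold (camera adjusted p = 2.2e-07, and adjusted p = 0.246 with an estimated correlation). Of 33 p53 targets 15 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.00933, and adjusted p = 0.275 with an estimated correlation). The medians were 0.35, 0.29 and 0.46 for p53 targets and 1.28, 1.31 and 1.51 for immediate early genes on shEp400 arrays 1, 2 and 3. Cdkn1a, the cell cycle inhibitor p21, rose 4.43-fold and Phlda3 3.81-fold, while Psrc1 fell 1.74-fold and Tigar 1.69-fold, a call lost without background correction and with the deposited matrix. Of 27 interferon response genes 15 rose and 0 fell, and adjusted over the list alone 16 rose. The class I gene H2-D1 rose 4.72-fold and Gbp2 4.43-fold (camera adjusted p = 3.52e-05, and adjusted p = 0.246 with an estimated correlation). The list's medians were 0.60, 0.93 and 0.75 on these arrays. Autophagy and lysosome genes rose in 17 of 26 cases and 0 fell, and adjusted over the list alone 19 rose. Gpnmb rose 5.08-fold and Cd63 3.93-fold (camera adjusted p = 4.12e-06, and adjusted p = 0.246 with an estimated correlation). Its medians were 0.48, 0.91 and 1.11 on the same arrays, and the feeder marker medians beside all 4 lists were 1.84, 2.23 and 2.43. The rises of these 4 lists, p53 targets included, were not told apart from a larger share of feeder-cell RNA. The unfolded protein and amino acid stress list did not pass (camera adjusted p = 0.0857): 11 of 35 rose and 5 fell, also adjusted over the list alone. Ddit3 rose 4.32-fold, Atf3, detected on 2 of 3 control arrays, 3.89-fold, Slc7a3 fell 3.84-fold and Psat1 2.16-fold. Heat shock genes did not pass either (camera adjusted p = 0.858), with 4 of 24 higher and 5 lower, and adjusted over the list alone 3 higher and 4 lower. Hspa1a rose 5.14-fold and Hspa1b, whose probe was detected on 2 of 3 control arrays, 3.64-fold, while Hspe1 fell 2.17-fold and Hspa4 1.76-fold. Without background correction the log2 changes shrank to 1.41 for Jun, 1.14 for Gbp2, 0.77 for Atf3, 1.62 for Hspa1a and 0.76 for Hspa1b.

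Metabolic lists went both ways. On shEp400 arrays 1, 2 and 3 the glycolysis and hypoxia medians were 0.40, 0.36 and 0.25. Those of cholesterol synthesis were -0.40, -0.40 and -0.63, and those of oxidative phosphorylation -0.18, -0.20 and -0.32. Feeder marker medians on these arrays were 1.84, 2.23 and 2.43. Of 25 glycolysis and hypoxia genes 9 rose and 1 fell, also adjusted over the list alone. P4ha2 rose 4.39-fold, Vegfa 3.46-fold and Pdk1 fell 2.06-fold (camera adjusted p = 0.013, and adjusted p = 0.418 with an estimated correlation). Without shEp400 replicate 1 this call was lost (adjusted p = 0.0586). Cholesterol synthesis genes fell in 9 of 21 cases and 0 rose, also adjusted over the list alone, among them Pmvk 1.98-fold and the regulator Srebf2 1.94-fold (camera adjusted p = 0.0157, and adjusted p = 0.275 with an estimated correlation). Oxidative phosphorylation genes fell in 12 of 48 cases and 0 rose, and adjusted over the list alone 2 fell. Atp5a1 fell 2.01-fold and Cox7b, detected on 2 of 3 shEp400 arrays, 1.83-fold (camera adjusted p = 0.0202, and adjusted p = 0.246 with an estimated correlation). The list's call was lost with cyclic loess (adjusted p = 0.0511) and among probes detected on all 6 arrays (adjusted p = 0.0683), and that of Cox7b in 3 of the 6 fits that left out 1 array. Cytoplasmic ribosomal protein genes did not pass (camera adjusted p = 0.935), with a median log2 change of -0.01, or 0.16 with cyclic loess. With 75th percentile scaling the median was -0.38 and the list was called lower (adjusted p = 0.00816), and so it was with centring on the probes detected on every array (-0.34, adjusted p = 0.0081), chosen after seeing the data. Rpl4 fell by 0.78 and Rpl30 by 0.58 on the log2 scale, 3 of 48 fell and 0 rose, and adjusted over the list alone 0 passed. The call of Rpl30 was lost without control replicate 1 or 3 or shEp400 replicate 2, with cyclic loess and with the mean of its probes. In all, camera called 18 of 26 lists, 10 up and 8 down, and 0 held with an estimated correlation, where 4 were at an unadjusted p under 0.05. By fry, which asks whether a list's genes move one way on balance, 22 lists passed.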

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

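The tests below were chosen after the results had been seen, apart from the other splits for the genes changed, the genes changed at least 1.5-fold and the lists, which were set before those splits were run. The dilution test was changed several times after its values had been seen, and its outcome differed between versions, so its p-values describe these genes and are no clean test. Of the 2148 probes above background without a gene symbol, which no comparison above uses, 814 changed (limma, Benjamini-Hochberg), 422 higher and 392 lower. They were singled out because they carry a signal outside the named genes.

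The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split alone, 1 of 10, gave 4251 changed genes, 2005 higher, 2246 lower and 3671 changed at least 1.5-fold, and the highest of the other splits gave 0 in limma for each, with up to 273 genes at an unadjusted p under 0.05. Every other split puts arrays of both groups on each side, so the difference between the groups adds to the residual spread. Few calls were therefore likely there whatever the cause of the difference, and the 0 decides nothing about chance. For gene lists, 1 of 10 splits gave as many as the real 18, and the highest of the others gave 14 by camera with the preset correlation. Splits that mix the groups keep part of their difference. The 14 lists therefore do not show how many camera calls where groups do not differ.

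The feeder fibroblast markers rose strongly, and of 34 measured 28 were detected on all 3 control arrays and 0 were in another list. A gradient along the slide is argued against, since the list's median differed by 1.77 on the log2 scale between the neighbouring arrays of different groups and by at most 0.38 between neighbours of one group, although a step between the parts of the slide cannot be excluded. A second list of fibroblast genes, written before its values were tabulated though some had been seen, had a median log2 change of 1.76, with 25 of 31 measured genes higher and 0 lower, and lay above all of 10000 random lists matched on expression, whose highest median was 0.59. A larger share of feeder-cell RNA in the knockdown samples may therefore contribute; Acta2, at 13.8, Lox, at 12.3, and Col1a1, at 9.80 and named outside the rule, are examples of the shEp400 log2 levels involved. Fibroblast-like differentiation of the knockdown cells, which would raise the same genes, was not tested.

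The 2-cell-stage-like genes also rose, with a median of 2.21 over the 14 called members. The called members carry 9 different symbol stems, so probes shared within 1 family cannot account for all of them. The list held several families from the start, so this count was nearly fixed in advance. Shared probes within the Tdpoz or the Tcstv genes were not tested. Over 6 alternatives of background correction and normalization the lowest median of the 14 called members was 1.69. These members were chosen by their rise with the main settings, so the value shows only that their rise was kept. A larger share of feeder-cell RNA was not told apart from an effect of the Ep400 knockdown. Within groups the members had a slope of -0.22 on the feeder markers (95% interval -1.56 to 1.12, 6 arrays). The interval holds both 0 and 0.96, the ratio of the group differences. A feeder share would give that ratio only if both means changed in proportion on the log2 scale. Puromycin selection and the state of the culture were not tested.

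Replication and mitosis genes fell, with a median of -1.06 over 71 genes. The choice of background correction and normalization is argued against as the cause, since the highest median over 6 alternatives was -0.87. All 6 bring the arrays to a common scale, so a shift in total RNA between the groups was not tested. The next comparison takes the pluripotency genes as changed by dilution alone. On that premise, dilution by feeder-cell RNA alone would not account for the fall of the 26 genes with control log2 levels above 11. Their median was -1.05 against -0.30 for 16 pluripotency genes (permutation test over genes, p = 4e-05). It was also lower without 5 that fibroblasts may express (permutation test, p = 0.00023), where the list means differed by -0.60 between arrays (95% interval -0.71 to -0.49). The premise does not hold for the pluripotency list as a whole, since dilution alone predicts the same fall for all its genes. The list's medians were -0.30 above level 11, -1.13 between 8 and 11 and -0.62 under 8. Fbxo15, one of the 16, rose 1.67-fold. The comparison therefore does not decide whether dilution is the whole cause. Over all members dilution cannot be told apart from a change within the ES cells: the fall exceeded that of the pluripotency list (-0.56, p = 0.00128), also adjusted for level (difference -0.34, p = 0.0081), but without 11 pluripotency genes that fibroblasts may express the adjusted difference was -0.25 (permutation test over genes, p = 0.0937), although the interval between arrays, -0.42 to -0.08, excluded 0. Between levels 8 and 11 the medians were -1.23 for 32 genes and -1.13 for 14 (permutation test, p = 0.647). Under 8 they were -0.87 for 13 and -0.62 for 6 (permutation test, p = 0.617). Dilution as part or the whole of the fall therefore stays open throughout.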

How the results depend on the processing

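No paired analysis was possible because the labels give the samples no replicate numbers. All settings fixed in advance kept the counts of genes changed, higher and lower within 1.5 times, and cyclic loess and 75th percentile scaling moved the median of all genes by 0.11 and -0.11 on the log2 scale. The count changed at least 1.5-fold fell from 3671 to 2016 without background correction and to 2156 with the deposited matrix, which also has none; both keep background in the signal, which shrinks folds. Ep400 lost its call with cyclic loess (-0.42, adjusted p = 0.0631) and without control replicate 1 (adjusted p = 0.0616); adjusted p over the other settings fixed in advance lay between 0.0028 and 0.0428, and log2 changes without 1 array lay between -0.63 and -0.50. Lists shifted numbered 0 with an estimated correlation and 22 with fry, against 18. The trophectoderm list, at 0.0497, lost its call in 11 settings fixed in advance, those of other chromatin remodellers and of oxidative phosphorylation in 2 each, and that of glycolysis and hypoxia in 1, which makes 16 list calls lost. List calls gained numbered 9: mesoderm and definitive endoderm 3, neuroectoderm 2, the unfolded protein list 2, ribosomal proteins 1 and Wnt targets 1. Calls of named genes gained numbered 18 (Zfp42 9, Nanog 5, Pou5f1 4). Log2 changes of named genes moved by over 1.5 times for 35 without background correction, 31 with the deposited matrix, 19 with normexp without negative controls, 4 with the mean of a gene's probes, 2 with array weights and 1 without shEp400 replicate 1. Calls of named genes were lost 42 times where an array was left out and 30 times under the other such settings. The latter were calls of Bmp4, Cox7b, Trrap and Wnt3a (4 each), Brdt and Klf4 (3 each), Rpl30 and Tigar (2 each), and Esrrb, Fbxo15, Kat5 and Yeats4 (1 each). Besides Klf4, Esrrb, Kat5, Yeats4 and Trrap, leaving out 1 array ended calls of Bmp4, Rpl30, Cox7b, Wnt3a, Apcdd1, Stmn2, Lefty1, Dppa3 and Fbxo15 and gave one for Pou5f1. The causes were not tested. Low signal limits dim probes, since the filter sets which are tested.

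Chosen after seeing the data, centring on the probes detected on every array gave 4433 changed genes, and leaving Ep400 out of its complex list gave 18 lists. With the feeder markers' mean as a covariate, limma called 0 genes changed, 0 higher, 0 lower and 0 changed at least 1.5-fold, with 863 at an unadjusted p under 0.05, and Ep400 had a log2 change of -1.51 (adjusted p = 0.628). The covariate correlated 0.98 with the group over the 6 arrays, so the fit can hardly separate them, and its values have wide errors. The log2 change took the opposite sign there, past no threshold, for Serpinb2 -1.43, Ccl5 -3.42, Gdf3 0.28, Qprt 1.87, Cdca7 0.10, Gli2 0.66, Pnma2 0.24, Tcl1 0.76, Lefty1 2.19, Rhox5 1.05, Mapt 2.19, Stmn2 1.03, Id2 -0.82, Krt8 -0.15, Bmp4 0.44, Igf2 -1.41, Hoxa5 -0.84, Cdkn1a -1.05, Phlda3 -1.80, Tigar 1.01, Ccnd1 -0.72, Tk1 0.64, Mcm2 0.51, Plk1 0.54, Nusap1 0.52, Rpl4 0.40, Vegfa -0.37, Pdk1 0.51, Pmvk 0.64, Srebf2 0.37, Ddit3 -1.37, H2-D1 -0.96, Notum 0.39, Gpnmb -2.27, Cd63 -0.43, Yeats4 0.23, H2az1 0.82, H2az2 0.58, Sox2 0.87, Klf4 1.57, Esrrb 1.15.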

Other observations

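Gene families were grouped by symbol stem after the data had been seen, and 149 families of at least 8 genes were tested with camera. Of these 14 passed, and those described below were chosen after their values were seen. Col, Dusp and Anxa genes also passed upward and Rad and Pla genes downward. Canonical histone genes passed upward with 20 of 49 higher and 10 lower (camera adjusted p = 0.0471). Pramel genes, leucine-rich repeat proteins of early embryos and germ cells, rose in 10 of 13 cases with 0 lower (median log2 change 1.89, adjusted p = 2.65e-05), and probes of such similar copies can read more than one of them. Besides Pramel17, which the rule names, Pramel37 rose by a log2 change of 2.82 and Pramel39 by 2.67, both chosen after their values were seen. Genes of the large subunit of the mitochondrial ribosome (Mrpl) fell in 21 of 46 cases and nucleoporins (Nup) in 11 of 16, with 0 higher in either (adjusted p = 0.000984 and 0.00233). Those of its small subunit (Mrps) did not pass (adjusted p = 0.164), with 7 of 27 lower and 1 higher. Exosome subunits (Exosc) fell in 5 of 8 cases, RNA helicases (Ddx) in 11 of 25 and RNA polymerase subunits (Polr) in 7 of 18, with 0 higher (adjusted p = 0.0251, 0.00761 and 0.0236). Directions of these medians were the same under every scaling alternative run. With an estimated correlation the adjusted p was 0.772 for each.

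Matrix metalloproteases (Mmp) rose in 8 of 11 cases and chemokines (Ccl) in 5 of 9, with 0 lower in either (adjusted p = 0.0063 and 0.0236, and 0.772 for each with an estimated correlation). The metalloprotease medians on shEp400 arrays 1, 2 and 3 were 0.84, 1.71 and 1.86, where feeder marker medians were 1.84, 2.23 and 2.43, and the chemokine medians were 1.58, 2.53 and 1.16. Hprt was chosen after its values were seen, since in an ES line that lacks it the signal would come from the feeder cells. The labels do not name the line, and this was not tested. Hprt had a log2 level of 8.40 in control and 10.9 in shEp400 cells (log2 change 2.53, SE 0.25, limma adjusted p = 8.95e-05), and its difference from control was 1.95, 2.66 and 2.98 on shEp400 arrays 1, 2 and 3.

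The mean of each called list's called members was also set against that of the feeder markers within groups over the 6 arrays (3 residual degrees of freedom), a comparison chosen after the data had been seen. Of 17 lists, the 95% interval of the slope excluded 0 for 4, where chance would give about 1 in 20 independent lists. These were the developmental regulators (slope 1.16, 0.57 to 1.75), autophagy and lysosome (1.10, 0.60 to 1.60), p53 targets (0.85, 0.15 to 1.56) and cholesterol synthesis (-0.51, -0.88 to -0.15). All slopes share the same 6 arrays, so the lists are not independent. A feeder share would give a slope equal to the ratio of the group differences only if both means changed in proportion on the log2 scale. The signals of 2 cell types add before the log2 step, so this need not be so. A missed ratio therefore does not argue against a feeder share. The interval held the ratio for 15 lists. It missed that ratio for the Tip60-p400 complex (slope -0.08, -0.21 to 0.04, ratio -0.36) and autophagy and lysosome (ratio 0.52). Slide position follows the same order on the shEp400 arrays and cannot be told apart. For extraembryonic endoderm the slope was 0.20 (-0.84 to 1.24) and for the interferon list 0.73 (-0.41 to 1.87).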
